A study of Sus scrofa with 6 samples.

How the data were processed

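Gene expression was measured by RNA sequencing (paired-end reads of 150 bp on a DNBSEQ instrument, per the labels) of total RNA from 6 pig libraries, 2 each of Sertoli cells (SC), induced pluripotent stem cells made from them (SC-piPSC) and induced pluripotent stem cells made from embryonic fibroblasts (PEF-piPSC). The deposited table holds FPKM values made by the authors for 26793 rows. The value multiplied by the row length was a whole multiple of a fixed step in 100% of values per library (tolerance 0.001), which gave the read count of each row and showed that the authors divided by the total count over all rows. Whether a count is a read or a read pair is not given in the sources used here, nor are the aligner, the genome build and the annotation. Coordinates are those of the deposited table. Of the named genes, 99.7% had the same start and 99.8% the same end as in the pig RefSeq annotation used here.

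Of the rows, 23643 carry a gene name, 7623 of them a LOC identifier, and 70 named rows lie on several sequences. The other 3150 rows carry none. Among them 108 rows span whole regions of the assembly and held 46.0% to 49.3% of the counts. On the sequences with such rows they held 0.98 to 1.042 counts per count in the other rows. Most reads were so counted in a gene and again in a region, and the FPKM denominators hold both counts. Another 3017 rows have an identifier but no gene name (2.04% to 2.83% of the counts), and 25 hold mitochondrial RNAs. Only named genes were used in the comparisons. No library was a copy of another. The counted totals were 72376853, 97308399, 50371295, 38256876, 29548913 and 32012101 for SC, SC-piPSC and PEF-piPSC, replicate 1 then 2. Agreement of replicates was compared with sampling noise by a chi-square per gene, whose median was 0.66 in SC, 1.52 in SC-piPSC and 40.74 in PEF-piPSC, where sampling noise alone gives 0.455.

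The groups, tests, gene lists, named genes and part of the alternatives were fixed before the data were examined, with a branch for counts and a branch for normalized values. As the table holds FPKM, the branch for normalized values was used. Genes with at least 1 FPKM in at least 2 libraries were tested (11195 genes). limma (version 3.58.1, with statmod 1.5.0, in R 4.3.3) was fitted to log2(FPKM + 1) of all 6 libraries in a model of the 3 groups, with 3 residual degrees of freedom and moderated variances that follow a trend with expression and are robust to outlying genes. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 changes are on the FPKM + 1 scale and understate the change of genes with low values. No fold is given against a group listed at 0. The 3 comparisons were SC-piPSC with SC, SC-piPSC with PEF-piPSC, and PEF-piPSC with SC. The equal variance across groups that the fit assumes does not hold here, since the PEF-piPSC replicates spread far more than the others. Fits with array weights estimated by limma per group (10.4 for SC, 2.03 for SC-piPSC and 0.0471 for PEF-piPSC) were therefore added after the data were seen.

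There were 31 gene lists: core, naive-state and primed-state pluripotency, Wnt ligands (with ligand processing genes and R-spondins, where none of the 19 WNT genes passed the filter), Wnt receptors and transducers, secreted Wnt antagonists, beta-catenin targets, markers of Sertoli, Leydig, peritubular myoid and smooth muscle, germ, blood and endothelial cells, fibroblast and extracellular matrix genes, mesenchymal transition factors, epithelial genes, markers of trophectoderm, endoderm, mesoderm and neuroectoderm, S phase and mitosis genes, glycolysis, oxidative phosphorylation, chromatin and DNA methylation regulators, FGF, LIF and TGF-beta family signalling, imprinted genes, HOX genes, p53 targets and senescence, interferon-stimulated genes and Y-linked genes. Some genes stand on several lists, as KREMEN1 and APCDD1 do on those of secreted Wnt antagonists and beta-catenin targets. Both encode membrane proteins rather than secreted ones. Lists with at least 3 tested members were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, which left out the Y-linked list with 1 tested member. Beside it, camera with the correlation estimated from the data and fry were run. fry tests whether the genes of a list move, on balance, one way, and in its mixed form whether they change in either direction, and compares the list with no other genes. With an estimated correlation 0 lists were called in any comparison. At an unadjusted p under 0.05 there were 2 for SC-piPSC with SC, 3 for SC-piPSC with PEF-piPSC and 3 for PEF-piPSC with SC, where camera at the preset correlation called 9, 17 and 17, and fry 18, 23 and 21. The estimated form tests on the 3 residual degrees of freedom, and the preset form does not, so that few lists could pass the former. For SC-piPSC with SC, the mitosis list went from an adjusted p of 6.49e-05 to 0.244, though its estimated correlation was -0.01. The values with an estimated correlation therefore do not show that correlation between genes undoes a call.

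Genes named in the text are 19 fixed genes (POU5F1, SOX2, NANOG, LIN28A, SALL4, KLF4, MYC, CDH1, EPCAM, SOX9, WT1, GATA4, AMH, FSHR, INHA, VIM, CTNNB1, AXIN2 and LEF1), the 5 highest and 5 lowest log2 changes per comparison among called genes with a symbol, a mean of at least 10 FPKM in the higher group and groups that do not overlap, and up to 4 called genes per list and direction with a mean of at least 1 FPKM in the higher group. A gene under this rule is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

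The fit was tested on simulated data with the observed spread of each group (20 draws, 200 of 11195 genes changed). Far more genes were called in the data, so that the adjusted p was a stricter cut in these draws. The shares recovered and the false calls may therefore differ in the data. For SC-piPSC with SC it recovered 35.1% of changes of 1 and 60.5% of changes of 2 on the log2 scale, with 1.4 false calls on average. For SC-piPSC with PEF-piPSC it recovered 55.3% and 76.3% with 410.6 false calls, and for PEF-piPSC with SC 52.7% and 74.2% with 398.4. With array weights the fit recovered 95.2% and 99.7% for SC-piPSC with SC, with 52.1 false calls. For the comparisons with PEF-piPSC it recovered few changes: 0.6% and 21.3% for SC-piPSC with PEF-piPSC (7.7 false calls), and 0.7% and 14.4% for PEF-piPSC with SC (6.5 false calls).

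The alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, limma-voom on the recovered reads, only the 4 libraries of a comparison, a replicate block, and leaving out each library in turn, with the filter applied again. That filter drops genes expressed in 1 group alone when a library of the group is left out. Such genes pass the full filter only through that group, so that a count of list members higher there is partly set by the filter. Fits without 1 library on the 11195 genes of the full data were therefore added after the data were seen. Losses of lists are given from these unless the text says that the filter was applied again, and losses of single genes from the fits with the filter applied again. Of 278, 197 and 182 such losses among named genes, 248, 170 and 157 stayed with the 11195 genes (SC-piPSC vs SC, SC-piPSC vs PEF-piPSC and PEF-piPSC vs SC). Rescaling to a common total, median-of-ratios and upper-quartile scaling of the FPKM values, array weights, removal of the trend with gene length and limma's treat were added after the data were seen, as was a separate SC library for each line in the correlation of the lines' changes. The overlap of calls was compared with 100 simulations of unchanged groups. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.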

Results

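RNA sequencing measured gene expression in 6 pig libraries that fall into 3 groups of 2. The groups were Sertoli cells from testis (SC), induced pluripotent stem cells made from Sertoli cells (SC-piPSC) and induced pluripotent stem cells made from embryonic fibroblasts (PEF-piPSC). Counted totals recovered from the deposited FPKM values were 72376853 and 97308399 in SC, 50371295 and 38256876 in SC-piPSC, and 29548913 and 32012101 in PEF-piPSC. Named genes held 35202175, 47278401, 24887159, 18930041, 14354876 and 16603044 of these, in the same order. At these depths, 3 reads on 1 kb of exon corresponded to 0.0308 to 0.102 FPKM, a limit that covers counting error only. Between 8312 and 10069 named genes per library reached 1 FPKM. Nothing in the labels says that the replicates of a group came from separate animals or cultures, and the p-values rest on the spread between these libraries alone.

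Replicates of SC and of SC-piPSC were close, and those of PEF-piPSC were far apart. Across the 11195 genes tested, Pearson's r of log2(FPKM + 1) between replicates was 0.999 in SC, 0.996 in SC-piPSC and 0.895 in PEF-piPSC (genes are not independent replicates). The share of genes more than 2-fold apart was 0% in SC, 0.1% in SC-piPSC and 26.3% in PEF-piPSC. In the PEF-piPSC pair, long genes were lower in replicate 2. The median log2 difference, replicate 2 minus replicate 1, went from 0.52 in the 2799 shortest genes (median exonic length 1224 bp) to -0.88 in the 2799 longest (7524 bp). The proliferation gene MKI67, named after its values were seen, was at 33.9 and 2.81 FPKM in that pair. Mitochondrial genes took 5.14% and 11.92% of named-gene reads in PEF-piPSC, 6.75% and 7.47% in SC-piPSC, and 2.82% and 3.14% in SC. Between groups, r was 0.806 to 0.816 for SC and SC-piPSC, 0.692 to 0.72 for SC and PEF-piPSC, and 0.829 to 0.85 for the lines of stem cells.

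**Figure D1:**
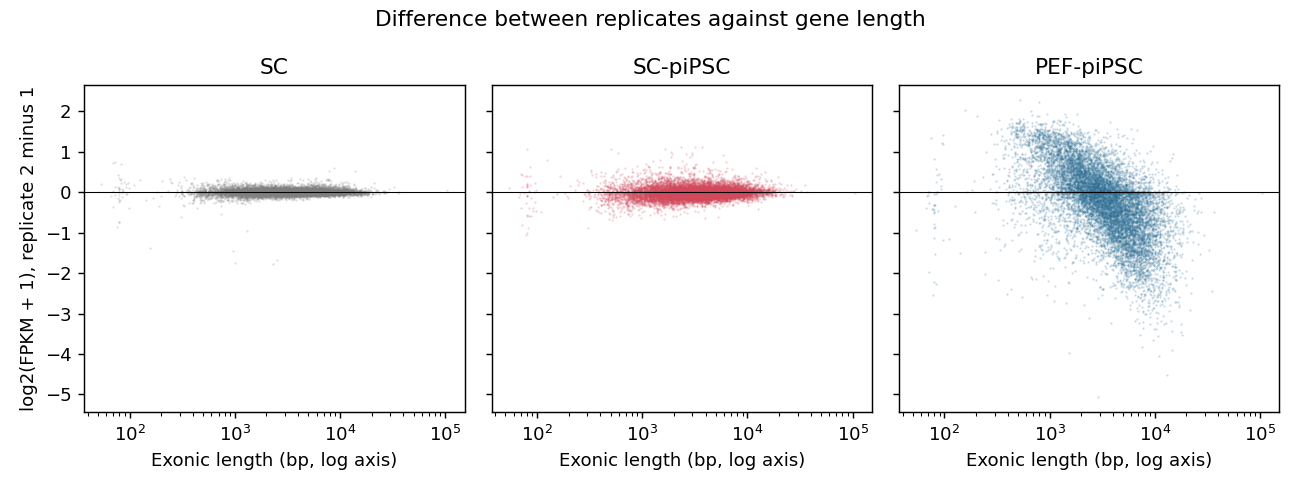
Difference between the replicates of each group, log2(FPKM + 1) of replicate 2 minus replicate 1, against exonic length in bp on a log axis, with a point per tested gene. The SC and SC-piPSC points lie along 0, and the PEF-piPSC points fall with length, with a Spearman correlation across genes of -0.62.

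SC-piPSC were compared with SC to ask how gene expression differed between the Sertoli cells and the stem cells made from them, with attention to the Wnt pathway that the series title names. POU5F1 and SOX2, transcription factors of the pluripotency network, were among the genes with the largest rises. POU5F1 (chromosome 7, 23564654 to 23570691) was at 0.0983 ± 0.00281 FPKM in SC and 52.8 ± 0.544 FPKM in SC-piPSC (SD, n = 2 each), a log2 change of 5.61 (adjusted p = 0.00015). SOX2 (chromosome 13, 119668476 to 119669435) was at 0.283 ± 0.0541 FPKM in SC and 179 ± 1.37 FPKM in SC-piPSC (SD, n = 2 each), a log2 change of 7.13 (adjusted p = 0.000221). KLF4 rose by 1.78 on the log2 scale (adjusted p = 0.00993) and MYC by 1.75 (adjusted p = 0.0343). The smooth muscle actin gene ACTA2 (chromosome 14, 100868145 to 100886732) had the largest fall among the named genes, from 2880 ± 27.4 to 6.86 ± 0.687 FPKM (SD, n = 2 each), a log2 change of -8.52 (adjusted p = 9.52e-05).

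Of 8 tested members of the core pluripotency list, 3 rose and none fell (3 and 0 adjusted over the list alone). The third was SALL4, at 2.64 ± 0.257 FPKM in SC-piPSC (SD, n = 2) and at 1 and 2 reads in the SC libraries (adjusted p = 0.0373). The list as a whole did not pass camera (adjusted p = 0.239, and adjusted p = 0.867 with an estimated correlation), but was called higher by fry (adjusted p = 0.02). LIN28A, an RNA-binding protein of early embryos, had 0 reads in SC and 12 and 9 reads in SC-piPSC (adjusted p = 0.117). It was called higher with array weights (2.3e-05), with only the 4 libraries (6.09e-05), with a pseudocount of 0.1 (0.00264) and with limma-voom (0.00248), and had the other sign with the length trend removed. NANOG was below the filter, with 0 reads in SC and 5 and 3 in SC-piPSC, and its row spans several sequences, so that its level is uncertain. The epithelial genes CDH1 and EPCAM were also below it, at no more than 0.312 and 0.0382 FPKM in SC-piPSC. In the fits without 1 library, POU5F1 and SOX2 stayed called in each fit that tested them. KLF4 was lost without either SC replicate 1 or SC replicate 2 (adjusted p = 0.107 and 0.119), and without SC-piPSC replicate 1 or 2 (0.0869 and 0.0827 on the genes of the full data, as the filter drops it there). MYC and SALL4 were lost without any 1 of the SC and SC-piPSC replicates, with adjusted p of 0.192 to 0.216 and 0.192 to 0.227.

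Among Wnt antagonists, all 11 tested members changed, 7 higher and 4 lower (7 and 4 adjusted over the list alone), and the list as a set did not pass camera (adjusted p = 0.706, and adjusted p = 0.867 with an estimated correlation). With fry the list was called lower (adjusted p = 0.02). Some members passed the filter only through their level in SC-piPSC, since 7 of the 11 were left without SC-piPSC replicate 1 or 2. Their rise was thus partly set by the filter. KREMEN1 and APCDD1, both higher, also count among the beta-catenin targets below. SFRP1, a secreted frizzled-related protein, rose from 2 ± 0.113 to 75.9 ± 1.54 FPKM (SD, n = 2 each, log2 change 4.68, adjusted p = 0.000102). KREMEN1, a co-receptor of the Dickkopf proteins, rose by 2.63 on the log2 scale (adjusted p = 0.000546). DKK2 and DKK3, of the Dickkopf family, fell, with log2 changes of -4.02 (adjusted p = 9.52e-05) and -3.76 (adjusted p = 0.000272). Of 19 tested beta-catenin target genes, 6 rose, 3 fell and 10 did not pass (6 and 4 adjusted over the list alone, adjusted p = 0.888 for the list). AXIN2, a feedback inhibitor of the pathway, went from 0.169 ± 0.00192 to 10.6 ± 0.557 FPKM (SD, n = 2 each, log2 change 3.31, adjusted p = 0.00951). That call was lost without any 1 of the SC and SC-piPSC replicates (0.0986 to 0.109). LGR5, the R-spondin receptor, rose by 2.27 (adjusted p = 0.00125) and CD44 fell, with a log2 change of -2.75 (adjusted p = 0.00256, and 0.0549 and 0.0543 without SC replicate 1 and 2, or 0.0335 and 0.0331 on the genes of the full data). LEF1 was at 0.119 ± 0.00365 and 1.70 ± 0.127 FPKM (SD, n = 2 each, adjusted p = 0.0969), and CTNNB1, which encodes beta-catenin, at 30.8 ± 0.0788 and 36.0 ± 2.11 FPKM (SD, n = 2 each, adjusted p = 0.585). LEF1 was called higher in 9 alternative fits, among them those without PEF-piPSC replicate 1 and 2 (1.16e-05 and 1.28e-05), with array weights (8.63e-09) and with only the 4 libraries (1.47e-05). CTNNB1 was called higher in 4, without PEF-piPSC replicate 1 and 2 (0.017 and 0.0167), with array weights (0.00877) and with only the 4 libraries (0.0178), and its log2 change of 0.21 turned to -0.16 with values rescaled to a common total and to -0.15 with median-of-ratios scaling. Of 28 receptors and transducers, 2 rose and 3 fell (1 and 3 adjusted over the list alone, adjusted p = 0.6). None of the 19 WNT genes on the ligand list passed the filter. Of its 4 tested members, the R-spondin genes RSPO1 and RSPO3 and the ligand processing genes WLS and PORCN, only WLS changed (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.888 for the list). WLS was lower by a log2 change of -1.34 (adjusted p = 0.017), a call lost without any 1 of the SC and SC-piPSC replicates (0.136 to 0.173).

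Of 18 tested Sertoli cell markers, 13 fell and 3 rose (13 and 3 adjusted over the list alone, adjusted p = 5.41e-06, but adjusted p = 0.412 with an estimated correlation). SOX9, which directs Sertoli cell fate, fell from 16.8 ± 0.176 to 0.522 ± 0.057 FPKM (SD, n = 2 each, adjusted p = 0.00226). GATA4 went from 17.1 ± 0.076 to 6.04 ± 0.829 FPKM (SD, n = 2 each, adjusted p = 0.00386) and WT1 from 7.92 ± 0.057 to 3.79 ± 0.58 FPKM (SD, n = 2 each, adjusted p = 0.012). GATA4 was lost without SC replicate 1, SC replicate 2 or SC-piPSC replicate 2 (0.0598 to 0.1, but 0.0462 without the last on the genes of the full data), and WT1 without any 1 of the SC and SC-piPSC replicates (0.0769 to 0.175). AMH, FSHR and INHA were below the filter. FSHR, the follicle-stimulating hormone receptor, had 108 and 128 reads in SC and 0 in the other 4 libraries. All 12 tested peritubular myoid and smooth muscle markers fell (12 adjusted over the list alone, adjusted p = 6.59e-12, but adjusted p = 0.244 with an estimated correlation). Desmin, DES, fell from 329 ± 0.0727 to 0.724 ± 0.115 FPKM (SD, n = 2 each). Of 26 fibroblast and extracellular matrix genes, 21 fell and none rose (22 and 0 adjusted over the list alone, adjusted p = 2.74e-13, but adjusted p = 0.412 with an estimated correlation). The collagen gene COL5A1 fell by a log2 change of -6.08 and lumican, LUM, by -4.90. Of 6 epithelial genes 4 fell (4 adjusted over the list alone, adjusted p = 0.00238, but adjusted p = 0.438 with an estimated correlation). The other 20 members were below the filter. Among them CDH1, CLDN7, OCLN and ST14, apart from CDH1 chosen after their values were seen, had 1 and 3, 0 and 1, 12 and 18, and 1 and 0 reads in SC, and 47 and 51, 53 and 51, 93 and 88, and 34 and 33 reads in SC-piPSC. Vimentin, VIM, was at 515 ± 4.49 and 895 ± 221 FPKM (SD, n = 2 each, adjusted p = 0.0948), and was called higher without PEF-piPSC replicate 1 and 2 (0.00616 and 0.00615), with array weights (9.78e-05) and with only the 4 libraries (0.00721).

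Of 26 S phase genes 19 rose and none fell (22 and 0 adjusted over the list alone, adjusted p = 4.97e-06, but adjusted p = 0.437 with an estimated correlation). Of 25 mitosis genes 14 rose and none fell (18 and 0 adjusted over the list alone, adjusted p = 6.49e-05, but adjusted p = 0.244 with an estimated correlation). The replication helicase gene MCM2 rose by 1.58 (adjusted p = 0.00267), a call lost without SC replicate 1, SC replicate 2 or SC-piPSC replicate 1 (0.0552 to 0.0924, but 0.0413 without the last on the genes of the full data). The cyclin gene CCNB1 rose by 1.84 (adjusted p = 0.0145), lost without any 1 of the SC and SC-piPSC replicates (0.116 to 0.146). Of 8 endothelial markers 6 rose (6 adjusted over the list alone, adjusted p = 0.00638, but adjusted p = 0.452 with an estimated correlation). With the filter applied again without SC-piPSC replicate 1 or 2, 3 of the 8 were tested. Some members thus passed the filter only through their level in SC-piPSC, so that their rise was partly set by the filter. CDH5, which encodes VE-cadherin, rose from 0.0292 ± 0.0111 to 17.1 ± 2.04 FPKM (SD, n = 2 each) and the VEGF receptor gene KDR from 0.0153 ± 0.00231 to 9.02 ± 0.596 FPKM (SD, n = 2 each). Of 4 tested germ cell markers 3 rose (3 adjusted over the list alone, adjusted p = 0.0377, but adjusted p = 0.412 with an estimated correlation). The list has 27 members, 21 of them in the file, and all but the 4 lay below the filter. Those went different ways, in examples chosen after their values were seen. DDX4 had 3 and 10 reads in SC and 6 and 5 in SC-piPSC. PIWIL4 went from 57 and 83 to 10 and 11 reads, and SYCP3 from 50 and 58 to 13 and 12. GFRA1 went from 4 and 3 to 89 and 50, and PRDM1 from 3 and 2 to 159 and 133. The receptor gene KIT rose from 2.07 ± 0.0434 to 142 ± 3.35 FPKM (SD, n = 2 each). The endothelial and germ cell lists were not called without PEF-piPSC replicate 1 or 2 (0.158 and 0.157 for endothelial, 0.132 and 0.132 for germ cell markers), nor with array weights. The chemokine gene CXCL13 had the largest rise among the named genes, from 0.354 ± 0.127 to 233 ± 4.28 FPKM (SD, n = 2 each, log2 change 7.44).

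In the limma fit, 3401 of 11195 genes changed between SC-piPSC and SC at an adjusted p under 0.05, 2002 higher and 1399 lower, and 2084 of them by at least 1 on the log2 scale (1135 higher, 949 lower). The replicates of the groups did not overlap for 10386 genes (92.8%, against 33.3% by chance). The median log2 change of all tested genes was 0.24, and the split turned with the scaling: 1001 higher and 1401 lower with values rescaled to a common total (median -0.03), 1137 and 1924 with median-of-ratios scaling (-0.03), 1280 and 1564 with upper-quartile scaling (0.1), and 1771 and 2273 with the length trend removed (0.02). The count fell when a SC or SC-piPSC library was left out and rose when a PEF-piPSC library was left out. Either replicate of a group gave a close count. It was 9320 with array weights and 9368 with only the 4 SC and SC-piPSC libraries. The fit shares 1 estimate of spread between groups, so that without a close replicate the wide PEF-piPSC pair weighs more in it. A call lost without 1 SC or SC-piPSC library therefore does not show that it rests on that library. No named gene lost its call with array weights. That fit called 9320 genes, with all 3401 of the main fit among them, and made 52.1 false calls in simulated data, so that keeping a call there says little. Of 127 named genes, 47 stayed called in each fit without 1 library that tested them, 23 were tested and called in all 6, and 57 were called in all 6 on the genes of the full data.

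**Figure D2:**
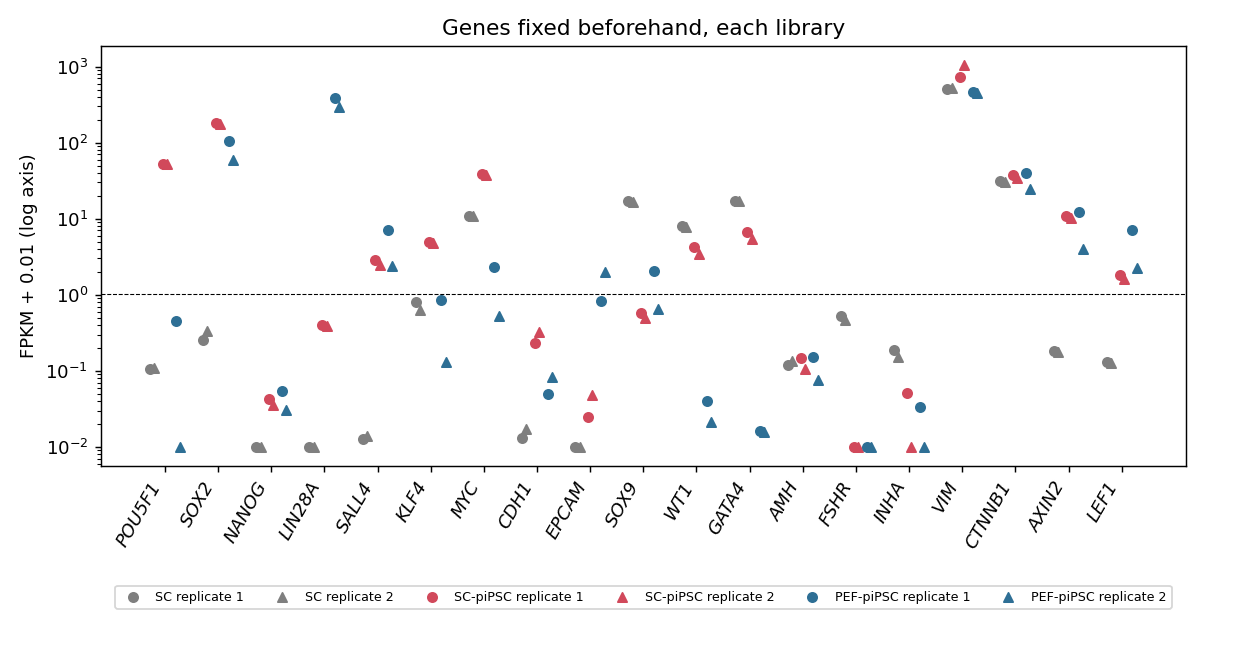
FPKM of 19 genes of pluripotency, epithelial and mesenchymal cells, Sertoli cells and the Wnt pathway, with 0.01 added, on a log axis. Colours mark the groups, circles and triangles replicate 1 and replicate 2, and the dashed line 1 FPKM, and POU5F1 is high in SC-piPSC alone (52.4 and 53.2 FPKM), LIN28A in PEF-piPSC alone (382 and 297 FPKM), and SOX2 in both lines.

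SC-piPSC were compared with PEF-piPSC to ask how stem cells from Sertoli cells differed from those made from embryonic fibroblasts. The cell of origin cannot be told apart here from donor animal, line, culture or preparation, which the labels do not describe. The lines also differed in reads of Y chromosome genes, at 1097.4 and 1156.3 CPM in SC-piPSC and 150.5 and 154.6 in PEF-piPSC. POU5F1 was at 52.8 ± 0.544 FPKM in SC-piPSC and 0.224 ± 0.317 FPKM in PEF-piPSC (SD, n = 2 each, log2 change 5.48, adjusted p = 0.000323), where the libraries had 19 and 0 reads. LIN28A (chromosome 6, 83806178 to 83818550) was at 0.383 ± 0.00341 FPKM in SC-piPSC and 339 ± 59.9 FPKM in PEF-piPSC (SD, n = 2 each, log2 change -7.93, adjusted p = 0.000219). SOX2 was at 179 ± 1.37 and 82.6 ± 32.9 FPKM (SD, n = 2 each, adjusted p = 0.062), and was called higher in SC-piPSC with median-of-ratios and upper-quartile scaling (0.0394 and 0.0457). Its log2 change of 1.16 was 1.57 without PEF-piPSC replicate 1 and 0.75 without PEF-piPSC replicate 2. Fits with 1 PEF-piPSC library hold no estimate of the PEF-piPSC spread. MYC was higher in SC-piPSC by 4.14 on the log2 scale (adjusted p = 0.00366, and 0.0715 and 0.0725 without SC-piPSC replicate 1 and 2, or 0.0495 and 0.0494 on the genes of the full data) and KLF4 by 2.02 (adjusted p = 0.0086, and 0.0802 and 0.0824 without the same libraries on the genes of the full data).

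Of 8 core pluripotency genes, 1 was higher and 3 were lower in SC-piPSC (2 and 5 adjusted over the list alone, adjusted p = 0.0382, but adjusted p = 0.666 with an estimated correlation). That list was not called without PEF-piPSC replicate 1 (0.0901) or with quantile normalization (0.0827). Of 13 genes of the primed pluripotent state, 6 were lower and 1 higher (7 and 2 adjusted over the list alone, adjusted p = 0.00136, but adjusted p = 0.483 with an estimated correlation). With the filter applied again without PEF-piPSC replicate 1, 9 of these 13 and 4 of the 8 core genes were tested. Being lower in SC-piPSC was thus partly set by the filter. ZIC2, a zinc finger factor of early neural development, was at 0.15 ± 0.0354 FPKM in SC-piPSC and 23.0 ± 10.4 FPKM in PEF-piPSC (SD, n = 2 each, adjusted p = 0.00168).

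Of the 4 tested members of the Wnt ligand list, none of them a WNT gene, RSPO1, RSPO3 and WLS were lower in SC-piPSC (3 adjusted over the list alone, adjusted p = 0.00171, but adjusted p = 0.393 with an estimated correlation). The R-spondin gene RSPO3 was at 0.27 ± 0.0249 against 6.28 ± 2.11 FPKM (SD, n = 2 each, adjusted p = 0.00253, and 0.0588 and 0.064 without SC-piPSC replicate 1 and 2, or 0.039 and 0.0418 on the genes of the full data). RSPO1 was lost without the same libraries (0.0541 and 0.057, or 0.0346 and 0.0356 on the genes of the full data), and WLS without any 1 of the SC and SC-piPSC replicates (0.0578 to 0.145). The frizzled receptor genes FZD10 and FZD2 were lower, with log2 changes of -3.89 (adjusted p = 0.000219) and -2.75 (adjusted p = 0.000957). Of 11 Wnt antagonists, 6 were higher and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.0416, but adjusted p = 0.394 with an estimated correlation). With the filter applied again without SC-piPSC replicate 1 or 2, 7 of the 11 were tested, so that being higher was partly set by the filter. The antagonist call was lost without PEF-piPSC replicate 1 or 2 (0.46 and 0.0802), and with array weights or the length trend removed. SFRP1 was at 75.9 ± 1.54 FPKM in SC-piPSC and 0.145 ± 0.127 FPKM in PEF-piPSC (SD, n = 2 each, log2 change 6.07, adjusted p = 0.000219), and SFRP5 at 5.76 ± 0.0592 FPKM and listed at 0 in PEF-piPSC. Of 19 beta-catenin targets 6 were higher and 4 lower (6 and 4 adjusted over the list alone, adjusted p = 0.66). AXIN2 was at 10.6 ± 0.557 and 8.14 ± 5.83 FPKM (SD, n = 2 each, adjusted p = 0.521). Its log2 change of 0.51 was 1.21 without PEF-piPSC replicate 1 and -0.19 without PEF-piPSC replicate 2, fits with no estimate of the PEF-piPSC spread. NKD1, an inhibitor of the pathway, was lower in SC-piPSC by a log2 change of -3.92 (adjusted p = 0.00524, and 0.0765 and 0.0923 without SC-piPSC replicate 1 and 2).

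Of the fixed Sertoli cell transcription factors, GATA4 and WT1 were higher in SC-piPSC than in PEF-piPSC, and SOX9 was at 0.522 ± 0.057 against 1.34 ± 0.985 FPKM (SD, n = 2 each, adjusted p = 0.298). SOX9 was called lower with quantile normalization (0.0176). Its log2 change of -0.55 was -1 without PEF-piPSC replicate 2, a fit with no estimate of the PEF-piPSC spread. GATA4 was at 6.04 ± 0.829 FPKM against 0.00584 ± 0.00033 FPKM (SD, n = 2 each, adjusted p = 0.000609), with 1 read in each PEF-piPSC library, and WT1 at 3.79 ± 0.58 against 0.0207 ± 0.0135 FPKM (SD, n = 2 each, adjusted p = 0.00103). Of 18 Sertoli cell markers 8 were higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.0398, but adjusted p = 0.529 with an estimated correlation). The Sertoli call was lost without PEF-piPSC replicate 1 or 2 (0.114 and 0.587), and with quantile normalization, array weights or the length trend removed. Of 8 endothelial markers 7 were higher (7 adjusted over the list alone, adjusted p = 0.000126, but adjusted p = 0.393 with an estimated correlation). With the filter applied again without SC-piPSC replicate 1 or 2, 3 of the 8 were tested, so that being higher was partly set by the filter. The endothelial call was lost without PEF-piPSC replicate 1 with the filter applied again (0.0548), and held on the genes of the full data (0.0333). All 4 mesoderm markers were higher (4 adjusted over the list alone, adjusted p = 0.00255, but adjusted p = 0.393 with an estimated correlation), a list lost without PEF-piPSC replicate 1 (0.134). KDR is a member of both lists. Of the 17 mesoderm members 15 were in the file, and all but the 4 tested lay below the filter. With the filter applied again without SC-piPSC replicate 1, 2 of the 4 were tested. Some members thus passed the filter through their level in SC-piPSC, so that all being higher was partly set by the filter. Of 6 endoderm markers 3 were higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0439, but adjusted p = 0.394 with an estimated correlation). The endoderm call was lost without PEF-piPSC replicate 1 or 2 (0.442 and 0.0882), and with median-of-ratios or upper-quartile scaling. SOX17, a transcription factor on the endoderm and germ cell lists, was at 28.1 ± 1.31 FPKM (SD, n = 2) and listed at 0 in PEF-piPSC. Of the 4 germ cell markers that passed the filter 2 were higher (3 adjusted over the list alone, adjusted p = 0.0382, but adjusted p = 0.394 with an estimated correlation). The germ cell call was lost without PEF-piPSC replicate 1 or 2 (0.147 and 0.0653). CXCL13, at 233 ± 4.28 FPKM in SC-piPSC (SD, n = 2), was listed at 0 in PEF-piPSC, and the calcium-binding protein gene S100A6 was at 339 ± 54.3 against 0.53 ± 0.03 FPKM (SD, n = 2 each, adjusted p = 0.000219).

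Of 21 glycolysis genes, 10 were lower and 1 higher in SC-piPSC (13 and 1 adjusted over the list alone, adjusted p = 2.84e-05, but adjusted p = 0.393 with an estimated correlation). The enolase gene ENO1 was at 405 ± 68.8 FPKM in SC-piPSC and 1590 ± 263 FPKM in PEF-piPSC (SD, n = 2 each, adjusted p = 0.0086), a call lost without any 1 of the SC and SC-piPSC replicates (0.0613 to 0.126). The phosphofructokinase gene PFKP went the other way, at 50 ± 1.39 against 0.42 ± 0.168 FPKM (SD, n = 2 each, adjusted p = 0.000219). Of 26 S phase genes 6 were lower (6 adjusted over the list alone, adjusted p = 0.00131, but adjusted p = 0.478 with an estimated correlation). Of 28 oxidative phosphorylation genes none passed the limma test (0 adjusted over the list alone) while the list was lower (adjusted p = 0.0224, but adjusted p = 0.752 with an estimated correlation). It was lost with quantile normalization (0.186), and without SC-piPSC replicate 2 with the filter applied again (0.0509, or 0.0347 on the genes of the full data), and turned to the other direction without PEF-piPSC replicate 2 (0.161). Interferon-stimulated genes were higher in 10 of 16 members (12 adjusted over the list alone, adjusted p = 0.00136, but adjusted p = 0.393 with an estimated correlation). The p53 targets were higher in 9 of 21 (13 adjusted over the list alone, adjusted p = 0.00328, but adjusted p = 0.483 with an estimated correlation). Without PEF-piPSC replicate 1 neither list was called (0.114 and 0.156). Muscle markers were higher in 6 of 12 members (7 adjusted over the list alone, adjusted p = 0.0315, but adjusted p = 0.478 with an estimated correlation). Matrix genes were higher in 11 of 26, with 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.0382, but adjusted p = 0.685 with an estimated correlation). Both lists were lost without PEF-piPSC replicate 1 or 2 (0.134 and 0.0653 for muscle, 0.0871 and 0.201 for matrix), with quantile normalization and with values rescaled to a common total.

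In the limma fit, 2506 of 11195 genes differed between SC-piPSC and PEF-piPSC, 1694 higher and 812 lower in SC-piPSC, and 1576 of them by at least 1 on the log2 scale (1104 higher, 472 lower). The replicates of the groups did not overlap for 6475 genes (57.8%, against 33.3% by chance). With array weights, 41 named genes lost their call. In simulated data with the same spread per group the fit made 410.6 false calls on average, and the split was 1433 higher and 1471 lower with quantile normalization (median log2 change -0.05, against 0.13) and 1715 and 1563 with the length trend removed (-0.03). The count was 1073 and 1082 without SC replicate 1 and 2, 424 and 386 without SC-piPSC replicate 1 and 2, 8933 and 8048 without PEF-piPSC replicate 1 and 2, and 944 with array weights. On the genes of the full data, the counts without 1 library were 1186, 1180, 940, 896, 9272 and 8350. Of 117 named genes, 52 stayed called in each fit without 1 library that tested them, 29 were tested and called in all 6, and 59 were called in all 6 on the genes of the full data.

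**Figure D3:**
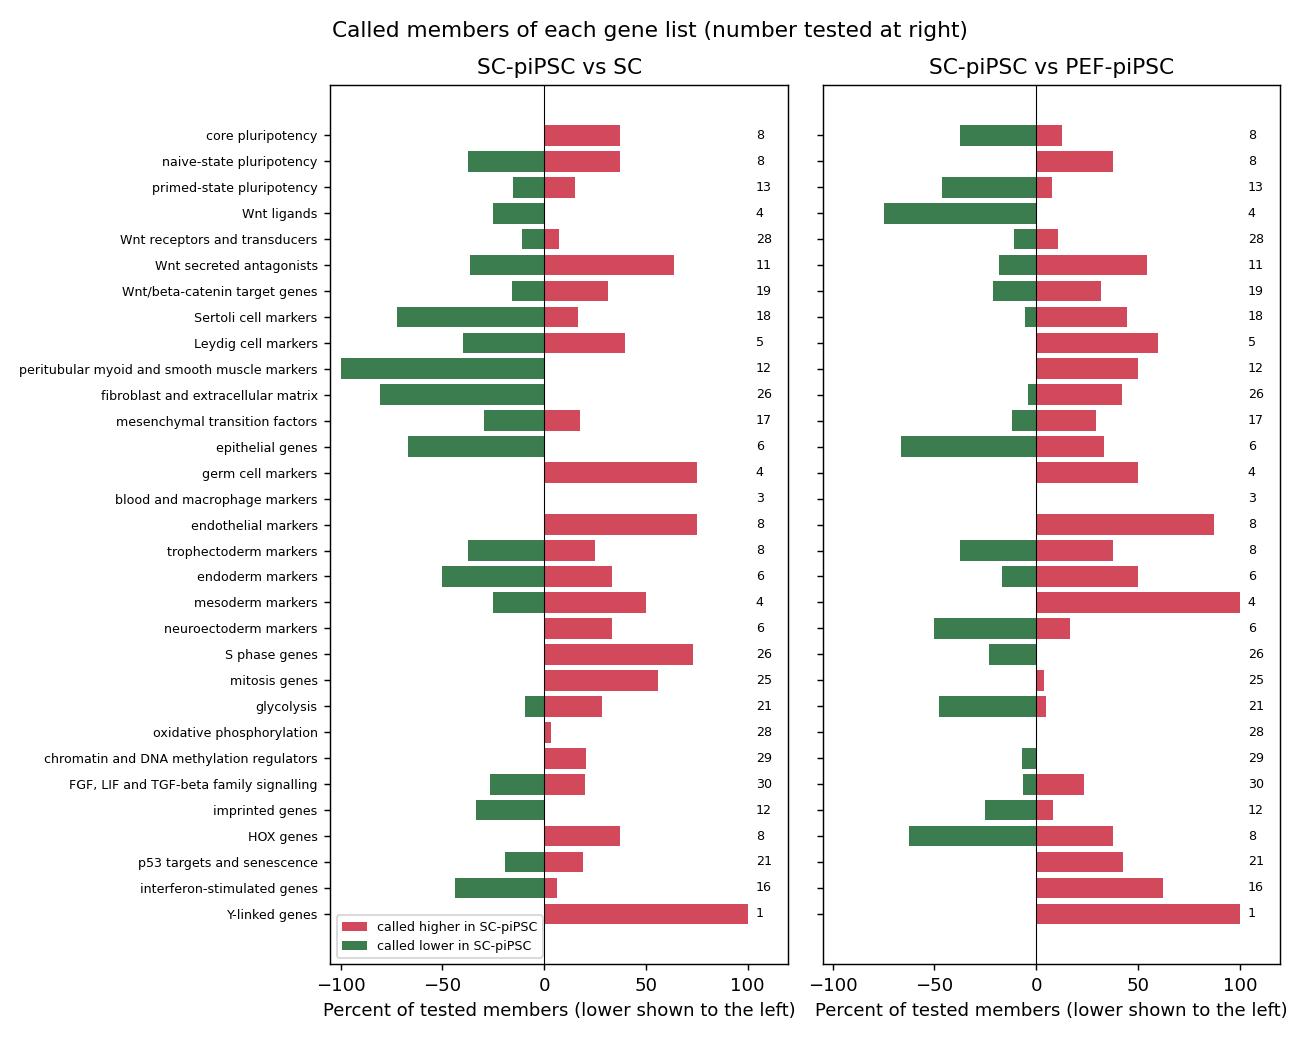
Percent of the tested members of each gene list called higher (right of 0) or lower (left of 0) in SC-piPSC, against SC on the left panel and against PEF-piPSC on the right, where the number tested stands beside each bar. All 12 peritubular myoid and smooth muscle markers were lower against SC, and 6 of 8 endothelial markers were higher against SC and 7 of 8 against PEF-piPSC. Some of the 8 endothelial markers passed the filter only through their level in SC-piPSC.

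PEF-piPSC were compared with SC as the other line against the same Sertoli cells. PEF-piPSC were made from another cell type, so that the comparison mixes the state and the origin of the cells. The retinoic acid-binding protein genes CRABP1 and CRABP2 were among the highest risers. CRABP1 was at 0.104 ± 0.0374 FPKM in SC and 3560 ± 3320 FPKM in PEF-piPSC (SD, n = 2 each, log2 change 11.24, adjusted p = 0.00078), and CRABP2 at 2.23 ± 0.149 and 678 ± 262 FPKM (SD, n = 2 each, log2 change 7.66, adjusted p = 0.000459). LIN28A was at 339 ± 59.9 FPKM in PEF-piPSC (SD, n = 2) and listed at 0 in SC (adjusted p = 8.83e-05), and SOX2 rose by 5.97 on the log2 scale (adjusted p = 0.000324). POU5F1 was at 0.0983 ± 0.00281 FPKM in SC and 0.224 ± 0.317 FPKM in PEF-piPSC (SD, n = 2 each, adjusted p = 0.656). Its log2 change of 0.13 was 0.4 without PEF-piPSC replicate 2 and -0.14 without PEF-piPSC replicate 1. It was -0.63 with limma-voom and -0.28 with the length trend removed. MYC fell, with a log2 change of -2.38 (adjusted p = 0.0109), a call lost without SC replicate 1 or 2.

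Of 8 core pluripotency genes 7 rose (7 adjusted over the list alone, adjusted p = 0.00188, but adjusted p = 0.56 with an estimated correlation). With the filter applied again without PEF-piPSC replicate 1, 4 of these 8 were tested. The same held for 9 of the 13 primed-state genes and 2 of the 4 Wnt ligand list members below. Rises on these lists were thus partly set by the filter. Of 13 primed-state genes 9 rose and 1 fell (9 and 2 adjusted over the list alone, adjusted p = 0.0448, but adjusted p = 0.644 with an estimated correlation). This call was lost without PEF-piPSC replicate 1 (0.0676). Of 8 naive-state genes 5 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.0486, but adjusted p = 0.576 with an estimated correlation). The naive-state call was lost without PEF-piPSC replicate 1 or 2 (0.0775 and 0.184), and with quantile normalization, rescaling to a common total, array weights or the length trend removed. Of the 4 tested members of the Wnt ligand list, none of them a WNT gene, RSPO1, RSPO3 and PORCN rose (3 adjusted over the list alone, adjusted p = 0.0346, but adjusted p = 0.308 with an estimated correlation), a call lost without PEF-piPSC replicate 1 or 2 (0.0826 and 0.0542) and with quantile normalization. PORCN was lost without SC replicate 1 and 2 (0.0896 and 0.101). FZD10, at 14.7 ± 0.305 FPKM in PEF-piPSC (SD, n = 2), was listed at 0 in SC, and NKD1 rose by 5.02 (adjusted p = 0.00151). Of 19 beta-catenin targets 8 rose and 6 fell (8 and 6 adjusted over the list alone, adjusted p = 0.939). AXIN2 rose by 2.80 (adjusted p = 0.0114, and 0.0873 and 0.0867 without SC replicate 1 and 2) and LEF1 by 2.19 (adjusted p = 0.0182, and 0.0631 to 0.113 without any 1 of the SC and SC-piPSC replicates). DKK3 fell from 312 ± 4.08 to 3.59 ± 0.352 FPKM (SD, n = 2 each, log2 change -6.09, adjusted p = 8.83e-05).

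Of 18 Sertoli cell markers 12 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 3.93e-05, but adjusted p = 0.308 with an estimated correlation), SOX9 with a log2 change of -2.99 (adjusted p = 0.00281). All 12 muscle markers fell (12 adjusted over the list alone, adjusted p = 7.73e-09, but adjusted p = 0.204 with an estimated correlation). Of 26 matrix genes 22 fell (23 adjusted over the list alone, adjusted p = 1.29e-09, but adjusted p = 0.347 with an estimated correlation). Of 26 S phase genes 22 rose (23 adjusted over the list alone, adjusted p = 5e-08, but adjusted p = 0.308 with an estimated correlation). Of 25 mitosis genes 15 rose (15 adjusted over the list alone, adjusted p = 0.00022, but adjusted p = 0.204 with an estimated correlation). Glycolysis genes rose in 16 of 21 members, with 1 lower (17 and 1 adjusted over the list alone, adjusted p = 0.00022, but adjusted p = 0.308 with an estimated correlation). Oxidative phosphorylation genes rose in 6 of 28 (4 adjusted over the list alone, adjusted p = 0.00168, but adjusted p = 0.687 with an estimated correlation), a call lost without PEF-piPSC replicate 2 (0.0542). Of 16 interferon-stimulated genes 11 fell (13 adjusted over the list alone, adjusted p = 3.93e-05, but adjusted p = 0.204 with an estimated correlation). Of 21 p53 targets 10 fell and 3 rose (11 and 4 adjusted over the list alone, adjusted p = 0.00483, but adjusted p = 0.431 with an estimated correlation), a call lost without PEF-piPSC replicate 1 (0.0864). VIM was at 515 ± 4.49 and 457 ± 18 FPKM (SD, n = 2 each, adjusted p = 0.643).

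In the limma fit, 4748 of 11195 genes changed between PEF-piPSC and SC, 2439 higher and 2309 lower, and 3246 of them by at least 1 on the log2 scale (1553 higher, 1693 lower). The replicates of the groups did not overlap for 8101 genes (72.4%, against 33.3% by chance). With array weights, 16 named genes lost their call. In simulated data the fit made 398.4 false calls on average, and the split was 1252 higher and 2362 lower with values rescaled to a common total (median log2 change -0.23, against 0.09) and 1707 and 2698 with median-of-ratios scaling (-0.04). The count was 801 and 811 without SC replicate 1 and 2, 2862 and 2868 without SC-piPSC replicate 1 and 2, 9421 and 9082 without PEF-piPSC replicate 1 and 2, and 2876 with array weights. On the genes of the full data, the counts without 1 library were 1642, 1653, 2982, 2987, 9760 and 9389. Of 133 named genes, 68 stayed called in each fit without 1 library that tested them, 49 were tested and called in all 6, and 81 were called in all 6 on the genes of the full data.

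The changes of the stem cell lines against SC were then set side by side. In both lines 2357 genes were called in the same direction, 1141 higher and 1216 lower, where independent lists would share 436.2 and 288.5, and 215 genes were called in opposite directions. POU5F1, CXCL13 and KIT rose in SC-piPSC, LIN28A in PEF-piPSC, and SOX2 and CRABP1 in both. The CRABP1 call in SC-piPSC was lost without any 1 of the SC and SC-piPSC replicates (adjusted p = 0.076 to 0.0841). The direct comparison of the lines differed for POU5F1, CXCL13, KIT, LIN28A and CRABP1 (CRABP1 adjusted p = 0.0138, and 0.142 and 0.15 without SC-piPSC replicate 1 and 2). The log2 changes of all tested genes had a correlation across genes of 0.71, against 0.04 in 100 simulations of unchanged groups with the same SC libraries, which shared 0 calls, and a covariance of 0.97 against 0.0015. Both comparisons use the same SC libraries. With a separate SC library for each line the correlation was 0.71 either way, and the covariance 0.96 and 0.97. The SC libraries were almost the same (r = 0.999), so that this split could hardly change the values. It does not take out what the lines share by being set against the same Sertoli cells. The simulations changed no gene, and so show only what the spread between replicates gives. The calls were not split, as 1 SC library would be left per comparison, and part of the excess of shared calls may come from the shared controls. The shared count was 131 and 137 without SC replicate 1 and 2, 649 and 687 without SC-piPSC replicate 1 and 2, and 6255 and 6702 without PEF-piPSC replicate 1 and 2. On the genes of the full data it was 621, 624, 807, 868, 6401 and 6819.

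**Figure D4:**
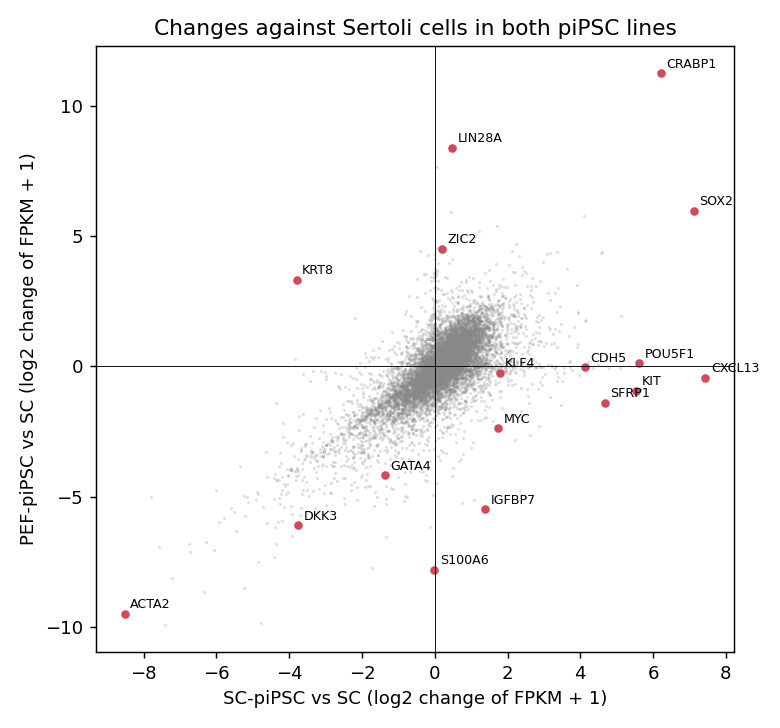
Log2 change of FPKM + 1 against SC of each tested gene, in SC-piPSC on the horizontal axis and in PEF-piPSC on the vertical axis, with some named genes in red. SOX2 and CRABP1 lie high on both axes, POU5F1, CXCL13 and KIT to the right (5.61, 7.44 and 5.54 in SC-piPSC), LIN28A near the top, where it is listed at 0 in SC and its place depends on the 1 added to FPKM, and ACTA2 at the lower left.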

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

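All tests in the 3 paragraphs that weigh explanations were chosen after the results were seen. The changes of 6 of the fixed genes against SC differed between the lines, tested by the contrast of SC-piPSC with PEF-piPSC on the log2(FPKM + 1) scale. The difference was 5.48 for POU5F1 (adjusted p = 0.000323), -7.93 for LIN28A (adjusted p = 0.000219), 2.02 for KLF4 (adjusted p = 0.0086), 4.14 for MYC (adjusted p = 0.00366), 2.23 for WT1 (adjusted p = 0.00103) and 2.80 for GATA4 (adjusted p = 0.000609). WT1 and GATA4 had 1 to 5 reads in the PEF-piPSC libraries, POU5F1 had 19 and 0 there, and LIN28A had 12 and 9 in SC-piPSC, so that these differences depend on the pseudocount. Outside the named genes, 554 of 1778 tested rows with an identifier but no gene name changed between SC-piPSC and SC, 296 higher and 258 lower.

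The PEF-piPSC replicates differed by more than 2-fold for 26.3% of genes, against 0% and 0.1% in the other pairs. A single scaling factor per library, as when a few genes take many reads, was argued against, since 27.2% of genes stayed over 2-fold apart with median-of-ratios scaling. Gene length may account for part of the difference, which followed exonic length with a Spearman correlation across genes of -0.62, but not for the whole, as 13% of genes stayed over 2-fold apart with that trend removed (Spearman 0.02 after removal). RNA quality, a separate preparation and separate cultures remain open, as no label describes them, and no biological explanation was tested.

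In SC-piPSC, POU5F1 and SOX2 were high while LIN28A was at 0.385 and 0.381 FPKM. A joint rise of the core pluripotency list could not be decided from the main fit. It called 1 of the 6 other tested members higher, and its recovery of true changes is not known for these data. In simulations it recovered 35.1% of log2 changes of 1. Those changed 200 of 11195 genes, where the data gave 3401 calls, so that recovery in the data may have been higher. With array weights, which recovered 95.2%, or with only the 4 libraries, 3 were called higher and 1 lower, so that not all of the 6 rose. With no filter 2 of 16 were called higher. Low depth was argued against, since 3 reads of LIN28A correspond to 0.127 FPKM in the shallower library. Reads from introduced copies of the reprogramming factors could give the pattern, as 4 of 4 factors asked (POU5F1, SOX2, KLF4 and MYC) were called higher, but cannot be told apart from the genes' own transcripts, since the positions of reads within genes are not given in the sources used here and the SOX2 row covers only 960 bp. A difference in the state of the cells stays open and untested.

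Endothelial markers were higher in SC-piPSC than in SC in 6 of 8 members. Some of the 8 passed the filter only through their level in SC-piPSC, so that this share was partly set by the filter. The scaling between groups was argued against, as the fewest called higher under any of 6 scalings was 6. Endothelial cells mixed into the culture may be a source of the 6 called members, and cannot be told apart from expression by the stem cells, because the levels in pure endothelial cells were not measured here. The most abundant listed transcripts in SC-piPSC were CLDN5 and CDH5 (18.4 and 17.1 FPKM), while ESAM did not differ detectably (log2 change -0.04, adjusted p = 0.843), ERG was at 0.657 and 0.692 FPKM in SC and 0.712 and 0.848 FPKM in SC-piPSC, ROBO4 had 55 and 78 reads in SC and 2 in each SC-piPSC library, and TEK and TIE1 were at no more than 0.0185 and 0.423 FPKM. KDR is also on the mesoderm list. ERG, ROBO4, TEK and TIE1, which were below the filter, and GJA5 (19.7 and 20.3 FPKM) and FLI1 (9.46 and 10.9 FPKM) were chosen after their values were seen.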

How the results depend on the processing

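The alternatives that rescale the values, remove the length trend, weight the libraries or use limma's treat, and the fits without 1 library on the genes of the full data, were chosen after the data were seen, the others before. The main counts were 3401 genes for SC-piPSC vs SC, 2506 for SC-piPSC vs PEF-piPSC and 4748 for PEF-piPSC vs SC. With no filter they were 5399, 4017 and 6293 of 23643 tested. In the same order, with array weights they were 9320, 944 and 2876, with only the 4 libraries of a comparison 9368, 1226 and 3024, and with limma's treat above a log2 change of 1, a stricter test, 712, 491 and 1102. Leaving out 1 library gave 360 to 9192, 386 to 8933 and 801 to 9421 with the filter applied again, and 1005 to 9360, 896 to 9272 and 1642 to 9760 on the genes of the full data, with a lone library assumed to vary like the other groups. The counts fell without a SC or SC-piPSC library and rose without a PEF-piPSC library in each comparison. Other settings (pseudocount 0.1, quantile normalization, limma-voom, rescaling to a common total, median-of-ratios, upper quartile, length trend removed) stayed within 1.5 times of the main counts. Some called genes changed sign: 8, 10 and 12 with the length trend removed, and 0, 35 and 3 with quantile normalization. No called gene changed sign in the fits without 1 library, and no called named gene in any setting. The log2 changes with array weights, a replicate block, only the 4 libraries or limma's treat are those of the main fit, so that no sign could change there.

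The main counts of called lists were 9, 17 and 17, and with fry, which asks a different question, 18, 23 and 21. With an estimated correlation, tested on 3 residual degrees of freedom that few lists could pass, they were 0, 0 and 0. Leaving out 1 library gave 8 to 10, 3 to 20 and 8 to 16 with the filter applied again, and 9 to 11, 6 to 18 and 10 to 17 on the genes of the full data. With the filter applied again, for SC-piPSC vs PEF-piPSC, the core pluripotency list turned to the other direction without PEF-piPSC replicate 1 (adjusted p = 0.758, in a range of 0.00276 to 0.933), where 4 of its 8 members were tested, and kept its direction on the genes of the full data (0.0901). The oxidative phosphorylation list turned in that comparison without PEF-piPSC replicate 2 (0.25, in a range of 1.18e-09 to 0.25). For PEF-piPSC vs SC, the list of chromatin and DNA methylation regulators turned without PEF-piPSC replicate 1 (0.905, in a range of 4.8e-05 to 0.905). The overlap of calls between SC-piPSC vs SC and PEF-piPSC vs SC was 2357, 1306 with a log2 change of at least 1 in both, a stricter rule, and 131 to 6702 without 1 library (621 to 6819 on the genes of the full data). Apart from the stricter rules, the larger set of genes with no filter, the filter applied again and the spread shared between groups, the cause was not tested.

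The labels do not say that replicate numbers pair libraries across groups. With a replicate block the counts were 2418, 1711 and 3916 and the lists 10, 16 and 17. The endoderm list was lost there for SC-piPSC vs PEF-piPSC (adjusted p = 0.0556). Its alternatives ranged from 0.000103 to 0.394, apart from the fits without a library on the genes of the full data, which this range leaves out. Deviations of the same number correlated at -0.02, -0.08 and -0.06 between groups.

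Reads could be recovered, and limma-voom was run on them. The other count-model alternatives (other count normalisations and count filters, count-model tests, their threshold test, and library size alone for the lists) were not run, as the branch for normalized values was used. Depth limits the low genes: 3 reads on 1 kb are 0.0308 FPKM in the deepest library and 0.102 in the shallowest.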

Other observations

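The read totals of the Y chromosome were taken after the data were seen, and no explanation was tested for the values here. The SC libraries held transcripts of genes listed as markers of other testis cells beside those of Sertoli cell markers. ACTA2 was at 2880 ± 27.4 FPKM and DES at 329 ± 0.0727 FPKM (SD, n = 2 each), while SOX9 was at 16.8 ± 0.176 FPKM and AMH at 0.109 and 0.124 FPKM. CYP11A1, the first enzyme of steroid synthesis and a Leydig cell marker, was at 19.5 ± 0.0619 FPKM in SC (SD, n = 2). Of 5 tested Leydig markers 2 fell and 2 rose in SC-piPSC (2 and 2 adjusted over the list alone, adjusted p = 0.347) and 3 fell in PEF-piPSC (3 adjusted over the list alone, adjusted p = 0.0222, but adjusted p = 0.308 with an estimated correlation). The latter call was lost without PEF-piPSC replicate 1 (0.232), and with quantile normalization. Named genes of the Y chromosome took 1449.8 and 1449.3 CPM of the named-gene reads in SC, 1097.4 and 1156.3 in SC-piPSC, and 150.5 and 154.6 in PEF-piPSC. EIF1AY, the tested member of the Y-linked list, was at 6.85 ± 0.0445, 10.7 ± 0.3 and 0.0613 ± 0.0597 FPKM (SD, n = 2 each), higher in SC-piPSC than in PEF-piPSC by 3.47 on the log2 scale (adjusted p = 0.000272).

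Of 8 tested HOX genes 3 were higher and 5 lower in SC-piPSC than in PEF-piPSC (3 and 5 adjusted over the list alone, adjusted p = 0.0706 for the list). HOXA2 was listed at 0 in SC, at 0.193 ± 0.0304 FPKM in SC-piPSC and at 5.87 ± 1.58 FPKM in PEF-piPSC (SD, n = 2 each, lower in SC-piPSC, adjusted p = 0.00139). In PEF-piPSC against SC 6 rose (7 adjusted over the list alone, adjusted p = 0.000997, but adjusted p = 0.308 with an estimated correlation). With the filter applied again without PEF-piPSC replicate 1, 3 of the 8 were tested. Being higher in PEF-piPSC, in either comparison, was thus partly set by the filter. In SC-piPSC 3 rose (3 adjusted over the list alone, adjusted p = 0.115). Of 6 neuroectoderm markers 4 rose in PEF-piPSC (4 adjusted over the list alone, adjusted p = 0.0279, but adjusted p = 0.431 with an estimated correlation), a call lost without PEF-piPSC replicate 1 (0.103). With the filter applied again without that library, 3 of the 6 neuroectoderm markers were tested, so that their rise was partly set by the filter. GBX2, a factor of the hindbrain border, had few reads in SC and 12.4 ± 3.81 FPKM in PEF-piPSC (SD, n = 2). In SC-piPSC 2 neuroectoderm markers rose (2 adjusted over the list alone, adjusted p = 0.368). Of 12 imprinted genes 3 were lower and 1 higher in SC-piPSC than in PEF-piPSC (4 and 1 adjusted over the list alone, adjusted p = 0.0398, but adjusted p = 0.483 with an estimated correlation). This call was lost without PEF-piPSC replicate 1 (0.14), without SC-piPSC replicate 1 with the filter applied again (0.0695, or 0.0461 on the genes of the full data), and with quantile normalization, upper-quartile scaling or the length trend removed. NNAT, an imprinted gene of neural cells, was at 0.525 ± 0.101 against 24.1 ± 6.26 FPKM (SD, n = 2 each, adjusted p = 0.000696). Against SC 4 imprinted genes fell in SC-piPSC (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0678). Of 16 interferon-stimulated genes 7 fell and 1 rose in SC-piPSC against SC (8 and 1 adjusted over the list alone, adjusted p = 0.0225, but adjusted p = 0.412 with an estimated correlation). Of 29 chromatin and DNA methylation regulators 7 rose in PEF-piPSC against SC (7 adjusted over the list alone, adjusted p = 0.0499, but adjusted p = 0.826 with an estimated correlation), a call lost without SC-piPSC replicate 1 or 2 (0.0508 and 0.0505) and turned without PEF-piPSC replicate 1 (0.959). With the filter applied again it was also lost without SC replicate 1 or 2 (0.0822 and 0.0938). It was lost with quantile normalization and with values rescaled to a common total. In SC-piPSC 6 rose (4 adjusted over the list alone, adjusted p = 0.174).

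The other lists did not pass camera for SC-piPSC against SC. Some of them were called by fry, which compares a list with no other genes. There the endoderm (adjusted p = 0.000187), mesoderm (0.000733) and glycolysis lists (0.0146) were higher, and the mesenchymal list (0.0139) lower. Among lists given above that camera did not call, fry called HOX genes higher (0.0138), and Leydig markers (0.000686) and imprinted genes (0.0302) lower. Higher and lower members were 3 and 3 of 8 for naive-state pluripotency (3 and 3 adjusted over the list alone, adjusted p = 0.442), 2 and 2 of 13 for primed-state pluripotency (2 and 2; 0.948), 3 and 5 of 17 for mesenchymal transition factors (3 and 5; 0.239), 0 and 0 of 3 for blood and macrophage markers (0 and 0; 0.893), 2 and 3 of 8 for trophectoderm (2 and 3; 0.227), 2 and 3 of 6 for endoderm (2 and 3; 0.571), and 2 and 1 of 4 for mesoderm (2 and 1; 0.442). They were 6 and 2 of 21 for glycolysis (6 and 2; 0.115), 1 and 0 of 28 for oxidative phosphorylation (0 and 0; 0.112), 6 and 8 of 30 for FGF, LIF and TGF-beta family signalling (7 and 9; 0.112), and 4 and 4 of 21 for p53 targets and senescence (6 and 4; 0.584). The median of the members and the camera test differed in sign for the Wnt ligands (median 0.17), Wnt receptors (0.19), mesenchymal factors (0.14), blood markers (0.28) and p53 targets (0.13), each tested as lower, and of these the mean was above 0 for the Wnt receptors and blood markers. camera and fry differed in direction for the Wnt antagonists, primed-state, Wnt receptor, blood and endoderm lists, and the endoderm list had a median of -0.65 and a mean of 0.54. In the other comparisons, the median and the test differed in sign for Wnt receptors, blood and trophectoderm markers (SC-piPSC vs PEF-piPSC) and for germ cell and blood markers (PEF-piPSC vs SC), and the mean and the median for the imprinted genes (PEF-piPSC vs SC). None of these lists was called by camera in the comparison named. For PEF-piPSC vs SC, camera and fry also differed in direction for Wnt receptors, beta-catenin targets and trophectoderm markers, and the means and medians for germ cell and blood markers.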
